A study of Mus musculus with 9 samples.

How the data were processed

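Expression was measured on Affymetrix MOE430 arrays in CD11b+ splenocytes of C57BL/6 mice. Per the labels' protocols, the cells were obtained by immunomagnetic positive selection from adherent spleen cells, and total RNA was extracted with a column kit and labelled with biotin. The 9 arrays comprise 6 threat animals, numbered 1 to 6, and 3 control pools of 2 animals, numbered 1-2, 3-4 and 5-6. Groups were taken from the stress label of each sample.

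The deposited values are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes, whose version and settings are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The log base is not stated and was taken from the values, which run from 0.607 to 13.567 with near-equal quantiles between arrays. The table holds 45101 probe sets. All 9 columns belong to the 9 samples. RMA gives no detection call, so the signal range that is background can only be approximated by a filter on dim probe sets. Normalization across arrays also assumes similar distributions, so a difference in the total RNA content of cells would not be seen.

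Gene names came from the platform's annotation, with symbols updated through the Entrez number to a RefSeq gene table of mouse assembly GRCm38.p6, used for names only. Of 45037 probe sets that are not controls, 34945 name 1 gene, 932 name several and 9160 name none here. In the table, 34741 of the 1-gene probe sets were matched and 204 kept the platform's symbol. Where several probe sets name a gene, the one with the highest mean over all arrays was used. Of 5623 genes with more than 1 tested probe set, 78 had probe sets called in both directions, and 2325 had both called and uncalled probe sets. Genes entered the test if that mean was at least the 40th percentile of all probe sets that are not controls, a log2 value of 2.66, which left 13078 of 18193 genes. Probe sets naming several genes or none were tested apart: of 648 with several genes 106 rose and 202 fell, and of 3617 without a gene 286 rose and 382 fell. The 64 control probe sets were left out of the gene test.

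The comparison, threat minus control, was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, arrays weighted equally, both groups sharing 1 estimate of the spread), and p-values were adjusted with the Benjamini-Hochberg method at 0.05. All tests were two-sided. The SE given beside a difference is limma's moderated standard error. Gene lists, 14 functional and 14 of cell types, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 28 lists, with an estimated correlation and with fry as alternatives. A further list of sex-linked genes was left out of that test. Of 504 genes in the lists, 420 were tested. A list's score is the mean of its genes on an array, compared between groups with an exact permutation test over all 84 divisions of the arrays into 6 and 3, whose smallest p is 0.0119. Lists share some tested genes. The proinflammatory list shares 4 with the list of inflammatory cytokines and chemokines. The list of immediate early and handling genes shares 5 with the cAMP list and 2 with the heat shock list.

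Lists, the test, its filter and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest rises and the 12 largest falls among called genes, from each list the 2 genes with the smallest p and the gene with the highest mean, and always Itgam, Nr3c1, Il1b, Tnf, Il6, Ly6c1, S100a8, S100a9 and a further gene that is not reported here. Immunoglobulin genes and members of near-identical families are called uncertain.

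The steps were tested on simulated data with the spread of these arrays and 13078 genes. With 50 genes changed at each size, limma recovered 42% of those changed by 0.25 on the log2 scale, and 100% at 0.5, at 1 and at 2, with 7 false calls in all. In a separate draw of simulated data camera called 1 of 28 lists, the one that had been shifted by 0.5. The simulated genes varied independently, so the check does not cover lists of correlated genes. The estimated correlation in these arrays was 0.67 for the granulocyte list.

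Array quality was checked through the control probe sets. The mean of the 18 hybridisation spike-ins was 0.082 higher in threat arrays (exact permutation p = 0.357). The beta-actin difference of 3' and 5' probe sets, a measure of RNA integrity, was 0.472 ± 0.063 in control and 0.357 ± 0.034 in threat arrays (SD, exact permutation p = 0.0238), and that of Gapdh differed by -0.036 (exact permutation p = 0.512).

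Alternatives included no filter or a filter at the 60th percentile, the mean of a gene's probe sets, preference for probe sets specific to a single transcript, each probe set on its own, quantile normalization, median centring, other settings of limma and of array weights, averaging of the threat animals in pairs, a replicate block and leaving out each array in turn. Chosen after the data were seen were limma's treat test against 1.2-fold and a Bonferroni adjustment. Figures were drawn with matplotlib 3.10.9.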

Results

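Gene expression was measured in CD11b+ splenocytes of C57BL/6 mice, which had been taken from adherent spleen cells by magnetic selection for the integrin CD11b. Affymetrix MOE430 arrays were hybridised with RNA of 6 animals exposed repeatedly to social threat, 1 array per animal, and with RNA of 6 animals kept under non-threatening conditions, pooled by 2 into 3 control arrays. The question of the design is whether expression differs between the 2 conditions. The 9 arrays had near-equal distributions, with medians between 3.19 and 3.22 on the log2 scale. Their number limits the precision of every difference below, and every control array is a pool of 2 animals where every threat array holds 1. No label gives a batch or a hybridisation day that could be tested.

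Threat and control cells differed widely. The acute-phase gene Saa3 rose by 5.27 on the log2 scale (SE 0.066, adjusted p = 1.2e-13), from 6.45 ± 0.18 (SD, n = 3 control pools) to 11.72 ± 0.028 (SD, n = 6 threat animals), a 38.5-fold difference. Granulocyte and precursor genes rose with it, among them the neutrophil collagenase Mmp8 by 2.76 (SE 0.060) and the granule proteases and peroxidase Prtn3 by 3.48 (SE 0.15) and Mpo by 2.95 (SE 0.20). Genes of natural killer cells and B cells fell, among them the granzyme gene Gzma, which fell by 3.11 (SE 0.13), and the B cell surface gene Ms4a1, which encodes CD20 and fell by 2.52 (SE 0.14). The sort antigen itself, Itgam, rose by 0.57 (SE 0.051, adjusted p = 1.7e-06).

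Of 13078 genes tested with limma, 5995 differed at a Benjamini-Hochberg adjusted p under 0.05, which is 45.8% of them. Threat animals had higher values in 3119 and lower values in 2876. Many of these differences were small: 4528 of the called genes differed by under 1.5-fold, and the median absolute difference of the called genes was 0.36 on the log2 scale. A difference of at least 1.5-fold was found in 1468 genes, 695 higher and 773 lower, of which 1467 also passed the test. At least 4-fold differences were seen in 29 genes that were higher and 46 that were lower. In 5471 genes (41.8%) the 6 threat values and the 3 control values did not overlap, where chance alone gives 2.38%. When each gene had to exceed 1.2-fold in limma's treat test, a setting chosen after the data were seen, 2162 genes passed.

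**Figure D1:**
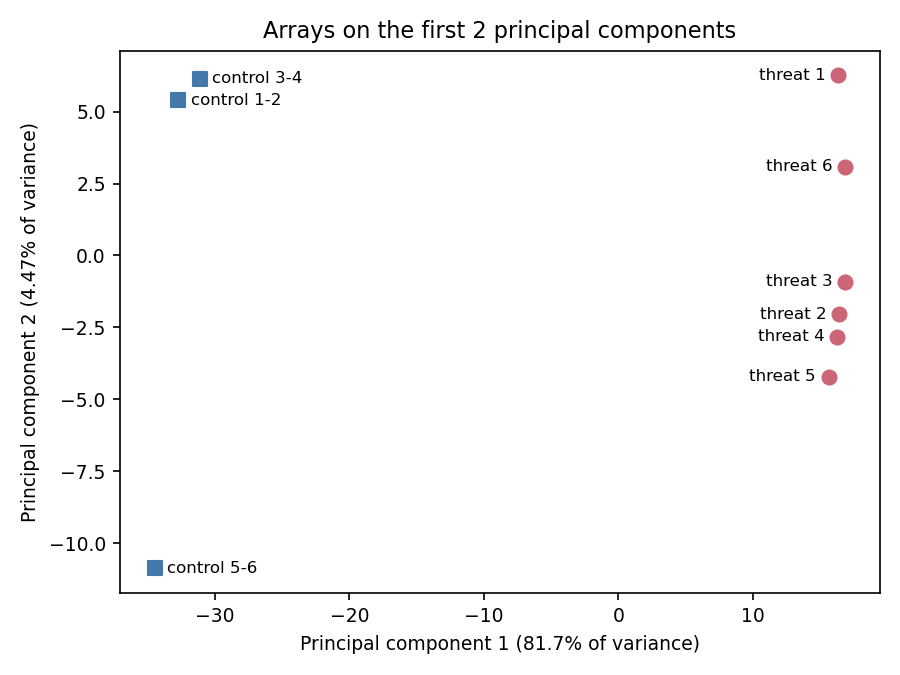
Positions of the 9 arrays on the first 2 principal components of the 13078 tested genes, with control pools as blue squares and threat animals as red circles. Component 1 holds 81.7% of the variance and parts the groups, and component 2 holds 4.47% and sets control pool 5-6 at -10.9 apart from the other control pools.

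Arrays resembled their own group more than the other. Pearson correlations across genes, which are not independent replicates, ran from 0.996 to 0.998 among control pools and from 0.996 to 0.998 among threat animals, against 0.972 to 0.977 between groups. The median SD of a gene was 0.0846 between single threat animals and 0.0832 between control pools, a variance ratio of 1.03 (exact p = 0.952 over the 84 divisions of the arrays into 6 and 3). Without control pool 5-6 the ratio was 2.36 (exact p = 0.571), and the number of called genes was 5300. All divisions but the real one mix threat and control arrays in a part. The difference between the groups then enters the spread, so neither p tests whether the spread differs.

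Beside Saa3, Prtn3, Mpo and Mmp8, the 12 largest rises were those of the stefin gene Stfa3 (5.31, SE 0.14), the epidermal growth factor receptor ligand Ereg (4.33, SE 0.11), the metalloreductase Steap4 (3.41, SE 0.069), the leucine-rich glycoprotein gene Lrg1 (3.34, SE 0.080), the uridine phosphorylase Upp1 (3.21, SE 0.068), Igfbp6 (3.03, SE 0.14), the retinol dehydrogenase Rdh12 (2.72, SE 0.065) and Ceacam10 (2.66, SE 0.12). Control values of Stfa3 and Ereg, 2.66 ± 0.38 and 2.12 ± 0.34 (SD, n = 3), lay near or under the filter value of 2.66, where signal cannot be told from background, so the size of their difference is approximate. Stfa3 also belongs to a family of near-identical copies, which makes its assignment uncertain.

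Of the 12 largest falls, 7 were of genes in the B cell or natural killer cell lists, Gzma and Ms4a1 included. Klra8, a natural killer cell receptor of a near-identical family and so uncertain, fell by 3.58 (SE 0.11) to 1.84 ± 0.17 (SD, n = 6), which lies in the background range. The B cell regulators Ebf1 and Pou2af1 fell by 2.59 each (SE 0.12 and 0.13). Falls of similar size were seen for the antigen receptor gene Cd79b (-2.41, SE 0.13), the IgM receptor gene Fcmr (-2.40, SE 0.11) and the natural killer cell regulator Eomes (-2.46, SE 0.13). The immunoglobulin gene Igha, uncertain as a member of a repeated family, fell by 2.54 (SE 0.23). The fatty acid desaturase Scd1 fell by 2.42 (SE 0.096), as did the cAMP-inducible regulators Nr4a2 (-2.42, SE 0.094) and Crem (-2.41, SE 0.065).

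**Figure D2:**
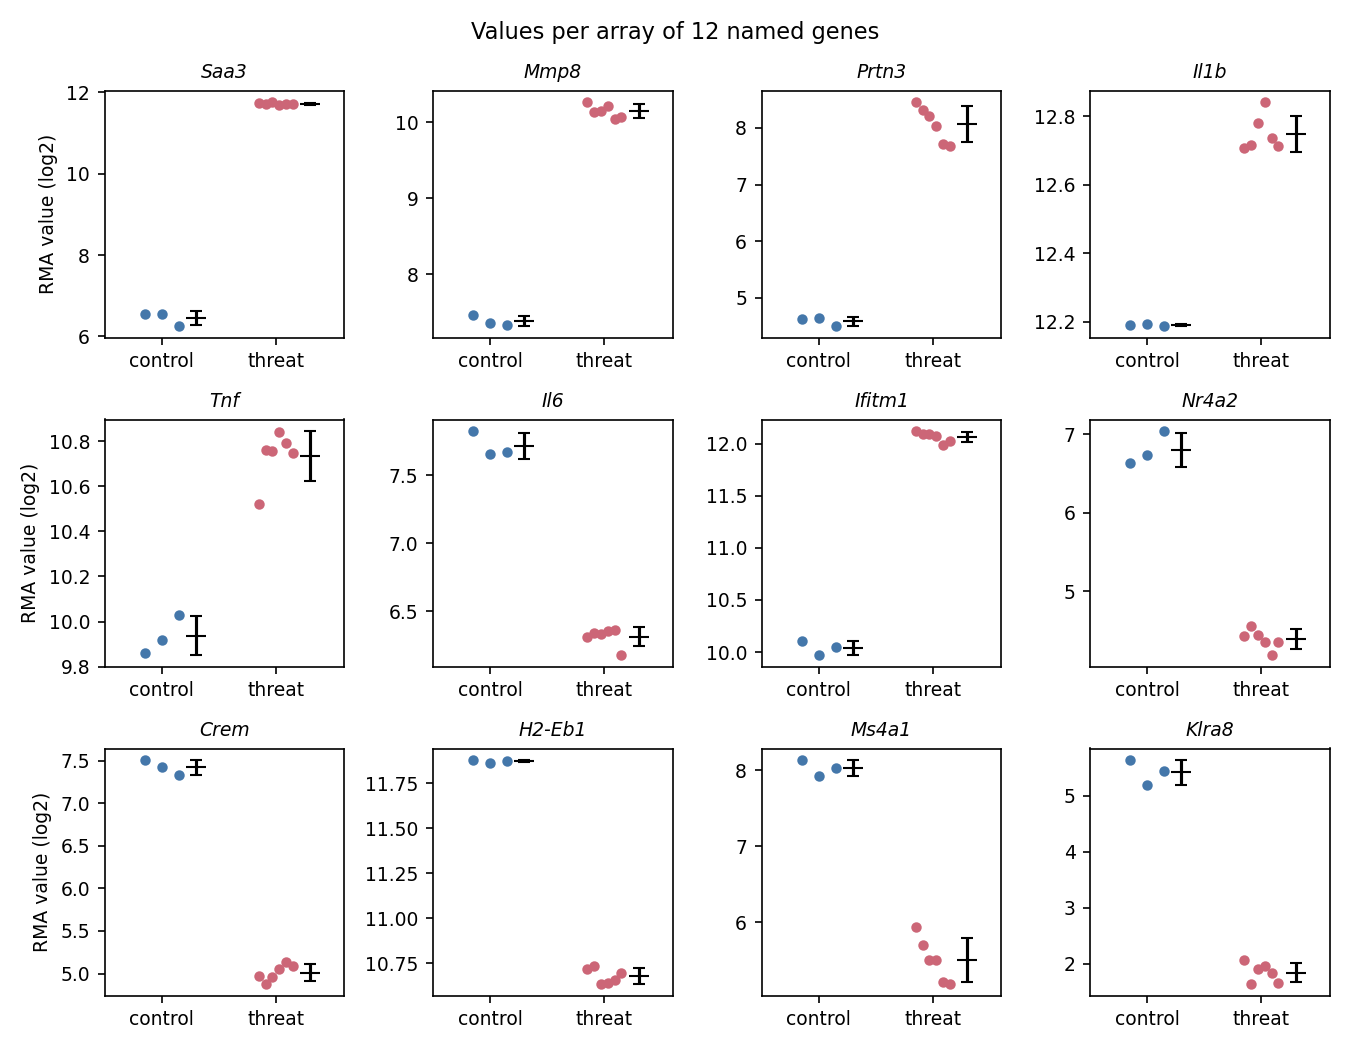
RMA values per array on the log2 scale for 12 genes named in the text, with 3 control pools in blue, 6 threat animals in red, and the group mean with its SD beside the points. Vertical scales differ between panels and do not start at 0. Saa3 lies at 11.72 in threat animals against 6.45 in control pools, and Klra8 at 1.84 against 5.42.

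Gene lists fixed before the data were examined were tested with camera, which asks whether a list's genes shift more than the other genes. At the preset inter-gene correlation of 0.01, 15 of 28 lists passed. With a correlation estimated from the arrays, 6 passed: cAMP and CREB-induced genes, antigen presentation by MHC class II, the unfolded protein and heat shock response, dendritic cells, T cells and natural killer cells. With the estimated correlation no other division of the arrays into 6 and 3 passed any list, although every other division mixes the groups.

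Markers of granulocytes and their precursors were higher in threat animals. Of 20 tested genes, 18 rose and none fell (19 adjusted over the list alone), with a median of 1.33 (adjusted p = 1.9e-11; adjusted p = 0.185 with an estimated correlation). Stfa2l1, a stefin gene of the same family as Stfa3 and so uncertain, rose by 2.03 (SE 0.065), and the calprotectin genes S100a8 and S100a9, which were already among the brightest in control cells, rose by 0.39 (SE 0.044) and 0.47 (SE 0.043). The mean of the list's genes per array was 1.42 higher in threat animals (exact permutation p = 0.0119, the smallest that 84 divisions can give and one that 23 of 29 list scores reach).

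Monocyte and macrophage markers split. In the Ly6C-high monocyte list, 8 of 11 genes rose and none fell, with a median of 0.48 (adjusted p = 0.0014; adjusted p = 0.185 with an estimated correlation). The haptoglobin gene Hp rose by 1.82 (SE 0.068) and Ifitm6 by 1.63 (SE 0.10), while S100a4 differed by -0.051 (adjusted p = 0.435) and the chemokine receptor gene Ccr2 by -0.13 (adjusted p = 0.0926). Hp and Ifitm6 were highest in threat animal 1 and lowest in threat animal 5, as was the granulocyte score. Their rises can therefore not be assigned to monocytes from the lists alone. In the Ly6C-low monocyte list, 3 of 12 genes rose and 7 fell, the median was -0.31 and the list did not pass (adjusted p = 0.0870). The peptidoglycan recognition gene Pglyrp1 rose by 1.84 (SE 0.099) there, and the scavenger receptor Cd36 fell by 1.68 (SE 0.096). In the red pulp and marginal zone macrophage list, 10 of 20 genes fell and 3 rose, with a median of -0.16 (adjusted p = 0.0102; adjusted p = 0.229 with an estimated correlation, and 0.118 at the stricter filter), and the median was -0.25 with probe sets specific to a single transcript. The prostaglandin dehydrogenase Hpgd fell by 2.31 (SE 0.079) and the phagocytic receptor Timd4 by 1.19 (SE 0.072), while the receptor gene Csf1r rose by 0.19 (SE 0.048, adjusted p = 0.0065).

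Dendritic cell markers and the genes of antigen presentation fell together. Of 15 dendritic cell genes, 12 fell and none rose, with a median of -0.69 (adjusted p = 6.8e-08, and adjusted p = 0.0139 with an estimated correlation). The list shares 1 tested gene with the natural killer cell list, Klrd1, which fell by 1.52 (SE 0.055). The homing receptor Ccr7 fell by 1.89 (SE 0.050) and the lectin Cd209a by 2.16 (SE 0.074), and Cd24a, the brightest of the list, differed by -0.0018 (adjusted p = 0.983). Of 14 genes of MHC class II presentation, 11 fell and none rose, with a median of -0.75 (adjusted p = 2.4e-07; adjusted p = 0.0144 with an estimated correlation). H2-Eb1, a chain of a class II molecule, fell by 1.195 (SE 0.044), and H2-Ob, a chain of a class II accessory molecule that B cells carry, by 2.19 (SE 0.10). Ctss, a lysosomal protease, differed by 0.045 (adjusted p = 0.428). B cells express class II genes as well, and B cell markers fell in the same arrays.

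Lymphocyte markers were mostly lower in threat animals. Most T and B cells carry no CD11b, whereas mature natural killer cells do. Of 14 B cell genes, 13 fell and none rose, with a median of -1.93 (adjusted p = 2.6e-11; adjusted p = 0.0854 with an estimated correlation). Cd79a fell by 2.31 (SE 0.097) and Fcrla by 2.02 (SE 0.076). The IgM heavy chain gene Ighm, the brightest of the list and uncertain as an immunoglobulin gene, fell by 1.13 (SE 0.091) from 11.35 ± 0.11 (SD, n = 3). Of 12 natural killer cell genes, 11 fell and none rose, with a median of -1.66 (adjusted p = 3.5e-10; adjusted p = 0.0144 with an estimated correlation), and Klrd1 fell by 1.52 (SE 0.055). Of 13 T cell genes, 8 fell and none rose, with a median of -0.33 (adjusted p = 0.0017; adjusted p = 0.0422 with an estimated correlation); Cd2, which natural killer and B cells express too, fell by 2.16 (SE 0.091), Cd5 by 0.96 (SE 0.11) and Il7r by 0.24 (SE 0.074, adjusted p = 0.0163). The call of Il7r was lost without control pool 3-4 (adjusted p = 0.0608) and without control pool 5-6 (adjusted p = 0.0651). Of 8 plasma cell and immunoglobulin genes, 5 fell and 1 rose, with a median of -0.99 (adjusted p = 0.0093; adjusted p = 0.178 with an estimated correlation) that ran from -1.67 at the stricter filter to -0.30 with no filter. Mzb1 fell by 1.67 (SE 0.083) and Iglv1, an uncertain variable segment, by 1.78 (SE 0.10).

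Genes induced through cAMP and the transcription factor CREB fell almost throughout. Of 17 tested genes, 16 fell and none rose, with a median of -0.97 (adjusted p = 2.2e-12; adjusted p = 0.0248 with an estimated correlation). The nuclear receptor gene Nr4a3 fell by 1.84 (SE 0.050) and the phosphatase gene Dusp1, the brightest of the list, by 0.85 (SE 0.051). In the list of immediate early and cell handling genes, which shares 5 genes with it, 12 of 20 fell and 1 rose, with a median of -0.27 (adjusted p = 1.7e-05; adjusted p = 0.0538 with an estimated correlation). Klf4 fell by 1.33 (SE 0.057), and Nfkbia differed by -0.022 (adjusted p = 0.724). In the unfolded protein and heat shock response, 12 of 18 genes fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.43 (adjusted p = 3.2e-06; adjusted p = 0.0201 with an estimated correlation). The inducible heat shock genes Hspa1a and Hspa1b, near-identical copies and so uncertain as single genes, fell by 2.14 (SE 0.097) and 2.12 (SE 0.073), and the endoplasmic reticulum chaperone Hspa5 by 0.49 (SE 0.044). In the same arrays the beta-actin difference of 3' and 5' probe sets was 0.472 in control and 0.357 in threat arrays (exact permutation p = 0.0238). That of Gapdh differed by -0.036 (exact permutation p = 0.512).

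Inflammatory genes moved in both directions. The cytokine genes Il1b and Tnf rose by 0.56 (SE 0.047, adjusted p = 8.2e-07) and 0.80 (SE 0.069, adjusted p = 1.1e-06), while Il6 fell by 1.40 (SE 0.058, adjusted p = 2.0e-09). Of 16 genes of the proinflammatory list, 5 rose and 10 fell, among them the transcription factor gene Fos (-1.26, SE 0.076), and the list did not pass (median -0.19, adjusted p = 0.139). Of 28 cytokine and chemokine genes, 12 rose and 13 fell (12 and 14 adjusted over the list alone) with a median of -0.11, and the list did not pass (adjusted p = 0.550). The growth factor gene Vegfa fell by 1.57 (SE 0.058). In the Toll-like receptor list, 9 of 23 genes rose and 5 fell, and the list did not pass (median 0.068, adjusted p = 0.139). Its inhibitory kinase gene Irak3 rose by 1.29 (SE 0.053), the adaptor gene Tirap by 0.86 (SE 0.051) and the lectin Clec4e by 0.35 (SE 0.050).

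Interferon-induced genes were mostly higher in threat animals. Of 30 tested genes of the type I interferon list, 21 rose and 1 fell, with a median of 0.49 (adjusted p = 1.7e-06; adjusted p = 0.0783 with an estimated correlation). Ifitm1, an interferon-induced membrane protein, rose by 2.02 (SE 0.050) and its relative Ifitm3 by 0.28 (SE 0.042). Irf8, a transcription factor of monocyte, dendritic cell and B cell development, was the gene that fell, by 1.70 (SE 0.067).

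The glucocorticoid receptor gene Nr3c1 differed by -0.0275 (SE 0.044, adjusted p = 0.650). Of 20 genes known as glucocorticoid-induced, 3 rose and 10 fell (4 and 11 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.0473; adjusted p = 0.191 with an estimated correlation). The transcription factor gene Cebpd rose by 1.63 (SE 0.049), and the metallothionein gene Mt1 by 1.48 (SE 0.057), although Mt1 differed by 0.080 (adjusted p = 0.422) when probe sets specific to a single transcript were preferred. These are 2 of the 3 genes that rose. The largest of the 10 falls were those of Tsc22d3 (-1.68, SE 0.078), Sesn1 (-1.19, SE 0.082) and Per1 (-0.88, SE 0.076), while Fkbp5 differed by -0.031 (adjusted p = 0.694). The list's call was lost at the stricter filter (adjusted p = 0.186), with threat animals averaged in number pairs (0.0575), with control pools at weight 2 (0.0507), without control pool 5-6 (0.0529), and without threat animal 1 (0.0595), 2 (0.0520) or 5 (0.0549). Its median was -0.14 with no filter. The monocyte gene Ly6c1 had no probe set that named it alone and was not analysed here.

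Cell cycle genes were higher in threat animals. Of 30 tested genes, 23 rose and 3 fell, with a median of 0.91 (adjusted p = 2.8e-05; adjusted p = 0.446 with an estimated correlation). The mitotic genes Ube2c and Ccnb2 rose by 1.73 and 1.53 (SE 0.14 each), and the replication clamp gene Pcna, the brightest of the list, fell by 0.45 (SE 0.050). Among the 6 threat animals the mean of the list per array followed that of the granulocyte list, a relation examined after the data were seen (Pearson r = 0.996, exact permutation p = 0.00139, adjusted over 4 relations 0.00556). Spearman's rho was 1 (exact permutation p = 0.00278, adjusted 0.0111), and r was 0.993 without the 2 animals farthest from the median. From threat animal 1 to threat animal 6 the granulocyte score went from 9.83 to 9.42 and the cell cycle score from 5.875 to 5.34. The B cell score fell in much the same order, from 5.24 to 4.90, so the relation is not particular to these 2 lists. The granulocyte and cell cycle scores also fell from control pool 1-2 (8.28 and 4.97) to control pool 5-6 (8.14 and 4.79). What the animal numbers stand for is not recorded.

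**Figure D3:**
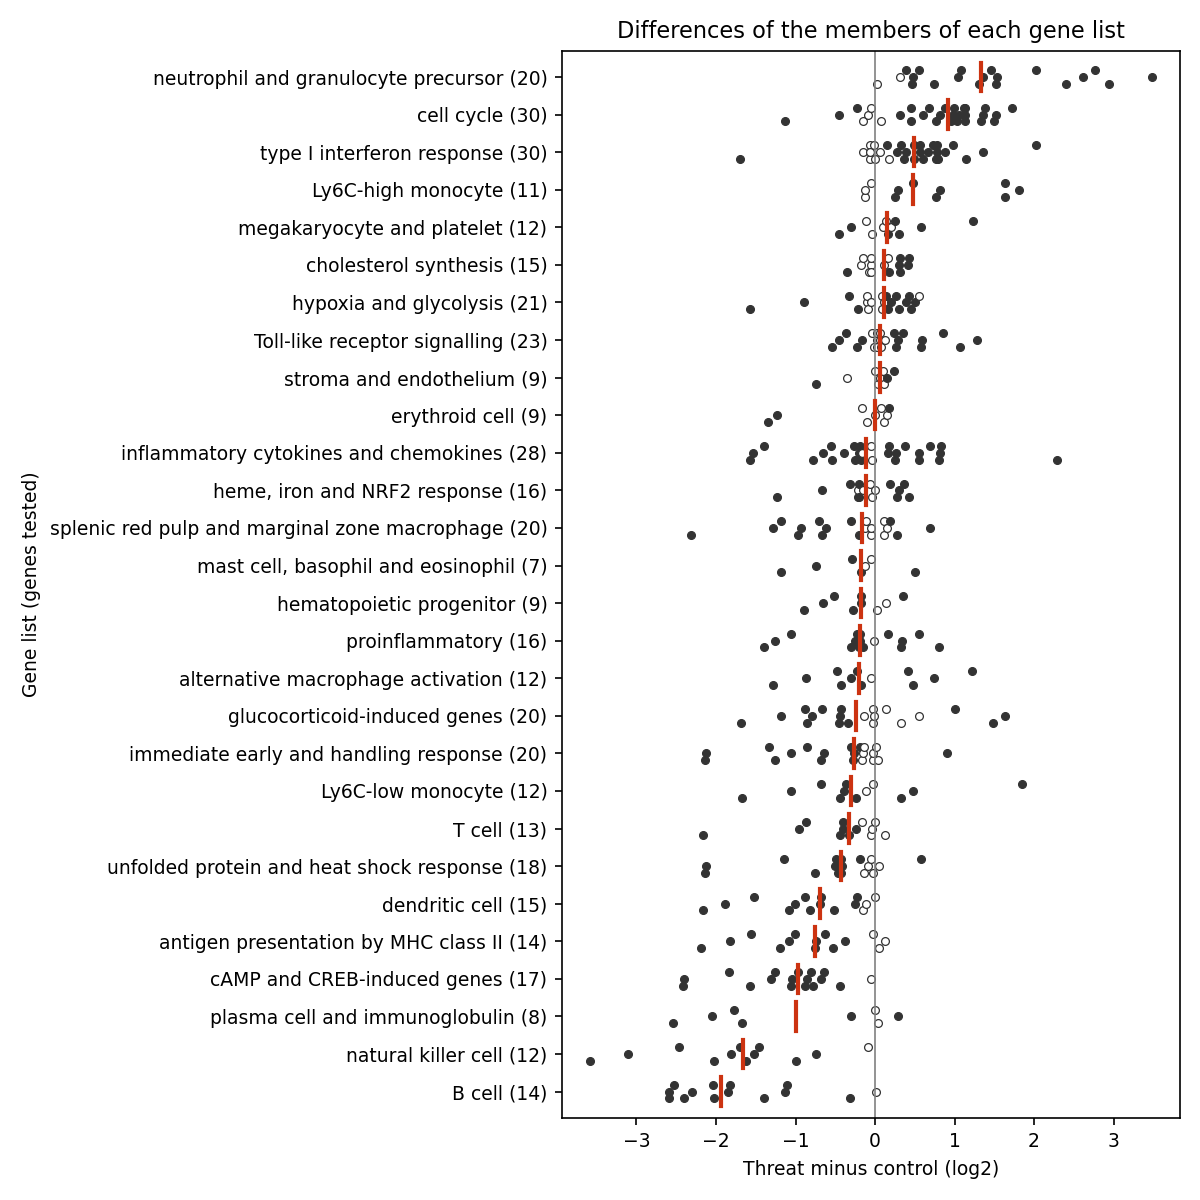
Difference between threat and control on the log2 scale for every tested member of the 28 lists, ordered by the list's median, which is drawn as a red bar. Filled points passed an adjusted p under 0.05 and open points did not. The granulocyte list has its median at 1.33 and the B cell list at -1.93.

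The remaining lists did not pass. Of 12 genes of alternative macrophage activation, 4 rose and 7 fell (median -0.20, adjusted p = 0.399). Trem2 rose by 1.22 (SE 0.050) there, but differed by 0.14 (adjusted p = 0.368) with the probe sets specific to a single transcript, and the chitinase-like gene Chil3, uncertain beside its close copy Chil4, rose by 0.74 (SE 0.053). Hypoxia and glycolysis genes (9 of 21 rose, 4 fell, median 0.12, adjusted p = 0.463) included Hif1a, which rose by 0.20 (SE 0.061), a call lost without control pool 1-2 (0.17, adjusted p = 0.0731), and Adm, which fell by 0.89 (SE 0.077). Cholesterol synthesis genes (6 of 15 rose, 1 fell, median 0.12, adjusted p = 0.399) included Nsdhl (0.42, SE 0.066), Fdps (0.32, SE 0.055) and Hmgcs1 (0.42, SE 0.095). Hmgcs1 differed by 0.20 (adjusted p = 0.0897) with the probe sets specific to a single transcript. Heme, iron and oxidative stress genes (5 of 16 rose, 6 fell, median -0.11, adjusted p = 0.305; 5 and 7 adjusted over the list alone) included the transferrin receptor Tfrc, which fell by 1.23 (SE 0.071), and the iron exporter Slc40a1, which rose by 0.28 (SE 0.059), while the ferritin gene Fth1 differed by -0.0038 (adjusted p = 0.950).

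The lists of other cell types did not pass either. In the erythroid list 1 of 9 genes rose and 2 fell, and Car2 fell by 1.34 (SE 0.065). The list's median was 0.00083 and its mean -0.26, so median and test differed in sign (adjusted p = 0.292). Megakaryocyte and platelet genes (5 of 12 rose, 2 fell, median 0.15, adjusted p = 0.292) included Gp1bb (1.23, SE 0.081) and Ppbp (0.58, SE 0.069). Mast cell, basophil and eosinophil genes (1 of 7 rose, 4 fell, median -0.17, adjusted p = 0.139) included Hdc (0.50, SE 0.065) and the eosinophil receptor Ccr3 (-1.18, SE 0.14). Among progenitor genes (1 of 9 rose, 6 fell, median -0.18, adjusted p = 0.133), Lmo2 rose by 0.35 (SE 0.047), while Kit and Cdk6 fell by 0.65 (SE 0.094) and 0.28 (SE 0.058). Stroma and endothelium genes (2 of 9 rose, 1 fell, 1 and 1 adjusted over the list alone) had a median of 0.066 and a mean of -0.045 (adjusted p = 0.890). Pecam1 fell by 0.75 (SE 0.094). Acta2 differed by 0.099 (adjusted p = 0.165) and was called higher with the mean of its probe sets (0.14, adjusted p = 0.0281). Pdgfrb rose by 0.24 (SE 0.079), a call lost without control pool 3-4 (adjusted p = 0.105) and without control pool 5-6 (adjusted p = 0.112).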

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

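The tests of a smaller share of lymphocytes, of dilution by granulocytes, of averaging in the pools, of cell handling and of control pool 5-6 were chosen only after the results were seen. The counts over other divisions of the arrays and the correlation of the cAMP score with the B and natural killer cell score were planned before their values were seen. The other 3 correlations, and the sorting of the divisions by the control pools they hold, were added after.

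Among the 6 threat animals, 128 values (list scores and named genes) were screened for an animal far from the others, and 5 stood out where chance gives about 6.4. Threat animal 1 was low for Tnf (10.52, the next animal at 10.75) and for the heme, iron and oxidative stress score (8.97). Threat animal 5 was low for Mzb1 (5.35) and high for Fth1 (13.36, a gap of little size). Threat animal 6 was low for Il6 (6.18). Tnf stayed above, and Il6 and Mzb1 below, every control pool in these animals.

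Control probe sets for Gapdh, which lie outside the gene test, were higher in threat arrays. The 5' probe set rose by 0.60 and the middle one by 0.62 (adjusted p = 9.9e-07 for each), and both differences kept their direction and size with quantile normalization (0.61 and 0.63) and with median centring (0.60 and 0.63). The flag took only rises of at least 1.5-fold. Below it, the 3' set of Gapdh rose by 0.56 (adjusted p = 3.2e-06) and the 5' set of beta-actin by 0.18 (adjusted p = 0.037). The transferrin receptor sets fell, the 3' one by 0.74 (adjusted p = 3.2e-06) and the middle one, in the background range, by 0.27 (adjusted p = 0.016).

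The gene counts were not matched by any other division, and 0.0119 is the smallest p that 84 divisions can give. Every other division mixes threat and control arrays in a part, which widens the spread within it. A count of 0 genes there is therefore a poor measure of chance. The real division called 5995 genes, and 1 of the 84 divisions, the real one, called as many, with 0 genes as the highest count of any other. The same holds for the 3119 higher and the 2876 lower genes, each matched by 1 of 84 divisions, the highest other being 0. At the preset correlation 15 lists passed, 6 of the 84 divisions passed as many and the highest other count was 16, so by this count chance cannot be excluded there. The count is a poor measure of chance, since the other 5 divisions set apart 3 threat animals, or 2 control pools with 1 threat animal, and so hold part of the real difference. The 45 divisions that set apart 1 control pool and 2 threat animals passed 0 to 4 lists. With an estimated correlation 6 lists passed, in 1 of 84 divisions, and the highest other count was 0, which has the same limit as the gene counts.

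The granulocyte list rose while the B and natural killer cell lists fell (adjusted p = 0.185, 0.0854 and 0.0144 with an estimated correlation, so only the natural killer cell list kept its call there). A lower share of lymphocytes alone would raise all remaining cell types alike, yet the granulocyte score rose by 1.49 relative to the monocyte and macrophage score (SD of that difference 0.077 in control and 0.20 in threat arrays, exact permutation p = 0.0119), which argues against it as the whole cause of the granulocyte rise. That reference joins lists that moved apart, and the relative rise was 0.75 against Ly6C-high monocytes, 1.62 against Ly6C-low monocytes and 1.82 against red pulp macrophages (exact permutation p = 0.0119 each). Dilution by granulocytes alone would lower all others alike, yet the B and natural killer cell score changed by -1.67 relative to the monocyte and macrophage score (exact permutation p = 0.0119), and by -2.41, -1.54 and -1.34 relative to the same 3 lists. Averaging the RNA of 2 animals in equal parts raises a pool above the mean of their logs. That argues against it as the cause of a granulocyte score 1.42 higher in threat animals (exact permutation p = 0.0119). Such averaging lifts a pool by less than its 2 animals differ. The B cell and natural killer cell scores were 1.72 and 1.76 lower in threat animals (SD 0.14 and 0.076 between threat animals, 0.11 and 0.10 between control pools). These values argue against averaging as the cause of the lymphocyte fall only if single control animals differed as little. Single control animals were not measured, so pooling stays open there. A change in both cell shares, a change in expression within cells, an unrecorded batch, and social threat itself, which was not tested apart from these, stay open as well.

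Genes induced by cAMP and heat shock genes fell, and social threat stays open as an untested explanation. Fewer B and natural killer cells as a source of cAMP-induced transcripts stay open. Among the 6 threat animals the cAMP score rose with the B and natural killer cell score (Pearson r = 0.843, exact permutation p = 0.0278, 0.940 without the 2 animals farthest from the median), but not on ranks (rho = 0.486, exact permutation p = 0.356). That r met the rule planned for this source. The verdict was set to undecided after the granulocyte relation, which was not planned, had been seen. The cAMP score rose as well with the granulocyte score (r = 0.922, exact permutation p = 0.0417, rho = 0.543, exact permutation p = 0.297) and the cell cycle score (r = 0.886, exact permutation p = 0.0444, rho = 0.543, exact permutation p = 0.297). These 2 relations rest on the 2 farthest animals, threat animals 5 and 6 (r = -0.282 and -0.333 without them). For the B and natural killer cell score the 2 farthest were threat animals 1 and 5. Its r of 0.940 therefore keeps threat animal 6 and cannot be compared with those 2 values. Adjusted over 4 relations, p was 0.0444 for each of these 3 r and 0.356 for each rho. Threat animals 5 and 6 were lowest in all 4 scores, so 6 animals are too few to decide. A difference in how long or how the cells were handled cannot be told apart from the condition. The cAMP median lay -0.82 from that of the 13 handling genes outside the cAMP and heat shock lists, so without Hspa1a and Hspa1b. Of these 13, 5 fell and 1 rose. The beta-actin difference of 3' and 5' probe sets is a measure of RNA integrity. It was 0.472 in control and 0.357 in threat arrays (exact permutation p = 0.0238). That of Gapdh differed by -0.036 (exact permutation p = 0.512).

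Control pools varied about as much as single threat animals, although a pool averages 2 animals. The variance ratio of 1.03 became 2.36 without control pool 5-6 (exact p = 0.571 over the divisions of the remaining arrays). The other divisions mix the groups, so that p does not test the spread. The 3 pools are too few to decide whether control pool 5-6 alone carries the spread.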

How the results depend on the processing

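Apart from treat and Bonferroni, chosen after the data were seen, the alternatives below were planned. Beside the main 5995 calls (3119 higher, 2876 lower), counts moved by over 1.5 times with each probe set tested on its own (9746, 4735 and 5011 probe sets), treat against 1.2-fold (2162, 1045 and 1117) and Bonferroni (1703, 826 and 877). The 1468 genes at 1.5-fold became 2440 probe sets, 3375 genes at the lower planned fold minimum and 518 at 2-fold. Leaving out 1 array gave 5300 to 5803 calls. The replicate block by number pair gave 5945 calls, 5787 of them shared, and 15 lists. Numbers were not found to pair the arrays, since deviations of same-numbered arrays correlated at 0.149, -0.152 and -0.029. Quantile normalization gave 6056 calls, 5741 shared. The lists that passed fell from 15 to 6 with an estimated correlation.

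The spread ratio of 1.03 became 0.979 with the stricter filter, 0.962 with median centring, 0.444 with threat animals averaged in number pairs, and 0.960 to 2.36 with 1 array left out. The sign turned for lists and genes that were not called: alternative macrophage activation (fry's direction up with a median of -0.20), mast cell genes (0.50 at the stricter filter) and stroma genes (test down with medians of 0.099 at the stricter filter and 0.040 with single-transcript probe sets, 0.052 without threat animal 3, and 0.026 to 0.090 over the arrays left out in turn). Values near 0 turned for Cd24a (0.0059 with quantile normalization, 0.0062 centred, -0.031 to 0.023 with 1 array left out), Eif2s3y (0.026 with the mean of probe sets, 0.0094 with quantile normalization, -0.056 to 0.022 with 1 array left out), Fth1 (0.0042 centred, -0.025 to 0.020 with 1 array left out), Nfkbia (0.013 with quantile normalization) and Nr3c1 (0.060 with the mean of probe sets). Fth1 was called lower with quantile normalization (-0.22), and Ctss higher (0.12). The Ly6C-low list passed with no filter (adjusted p = 0.0340). With fry, which does not compare a list with other genes, 22 lists passed, the added ones being proinflammatory (adjusted p = 0.00027), Toll-like receptor (9.3e-06), Ly6C-low (0.0015), erythroid (0.00071), platelet (0.00085), mast cell (0.022) and progenitor genes (0.00060). Of the values of named genes under all alternatives, 1939 kept direction and call, 15 turned, 8 lost and 6 gained a call. The cause of these moves was not tested. Signal near background limits the size of differences of dim genes.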

Other observations

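Families of genes chosen after the values were seen, by symbol, as were the members named, were tested with camera in the same way, 13 in all, and these tests are exploratory. The Gimap GTPases, which lymphocytes express strongly, fell in 8 of 8 tested genes (median -1.42, adjusted p = 5.5e-07; adjusted p = 0.124 with an estimated correlation), and 10 of 11 immunoglobulin variable segments fell, single segments being uncertain (median -1.26, adjusted p = 5.5e-07; adjusted p = 0.124 with an estimated correlation). Chemokine receptors fell in 11 of 14 genes (median -0.72, adjusted p = 1.0e-05; adjusted p = 0.124 with an estimated correlation), including Cxcr5 (-1.96) and Cx3cr1 (-0.68), whereas the neutrophil receptor Cxcr2 rose by 1.31. All 4 Fc gamma receptors rose (adjusted p = 0.00046; adjusted p = 0.0919 with an estimated correlation), Fcgr4 by 1.47 and Fcgr1 by 0.83. These directions held with quantile normalization and with median centring.

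Genes with symbols of respiratory complex I rose in 28 of 35 and fell in none (median 0.30, adjusted p = 1.2e-06, and adjusted p = 0.333 with an estimated correlation). Among the 35 are Ndufa4 (0.36, called) and Ndufa4l2 (0.056, not called), which are not complex I subunits. Ribosomal protein genes fell in 28 of 43 and rose in 2 (median -0.17, adjusted p = 1.0e-05, and adjusted p = 0.254 with an estimated correlation). Both directions held with quantile normalization (medians 0.30 and -0.13) and with median centring (0.31 and -0.16). Tubulins fell in 6 of 12 and rose in 1 (median -0.15, adjusted p = 0.0482; adjusted p = 0.199 with an estimated correlation). Matrix metalloproteinases (6 of 12 rose, 2 fell, adjusted p = 0.104) included Mmp14 (1.94) and Mmp12 (-1.02). Clec4 lectins (4 of 8 rose, 1 fell, adjusted p = 0.109), genes with proteasome symbols (14 of 38 rose, 3 fell, adjusted p = 0.109), integrin subunits (7 of 21 rose, 4 fell, adjusted p = 0.316), vacuolar ATPase subunits (5 of 15 rose, 2 fell, adjusted p = 0.589) and interleukin receptors (5 of 26 rose, 6 fell, adjusted p = 0.838) did not pass. The genes with proteasome symbols include Psmc3ip, which is not a subunit and was not called.

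The list of sex-linked genes was left out of the list test. Of its 4 tested genes 1 rose and none fell (2 and 1 adjusted over the list alone), Kdm5d by 0.34 (SE 0.086, adjusted p = 0.0063), while Uty and Eif2s3y differed by -0.13 (adjusted p = 0.0548) and -0.021 (adjusted p = 0.846). Xist, the remaining tested gene, was not called, but was among the 2 that rose adjusted over the list alone. Uty was called lower with probe sets specific to a single transcript (-0.35, adjusted p = 0.00067), with control pools at weight 2 (adjusted p = 0.0471) and without control pool 3-4 (-0.17, adjusted p = 0.0379).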
